A study of Homo sapiens with 60 samples.

How the data were processed

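RNA of cultured human cells was measured on 60 one-colour Agilent whole-genome arrays, 3 arrays in each of 20 groups. LNCaP prostate cancer cells gave 39 arrays, prostaspheres (prostate cells grown as floating spheres) 12, and MCF-7 breast cancer cells 9. The labels give triplicates and do not say whether these were separate cultures. Growth and treatment are described for LNCaP only. LNCaP cells were hormone-starved for 3 days and then treated for 24 h with 10 nM dihydrotestosterone (DHT) or 100 nM of another ligand.

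Per the file headers, the scanner files hold spot intensity read by Agilent Feature Extraction, version 9.5.3.1 on 9 arrays, 10.5.1.1 on 6 and 10.7.3.1 on 45. Their processed signal is background-subtracted and spatially detrended within an array and is not normalized between arrays. The deposited value table holds linear intensity that the authors set to one common distribution over all 60 arrays by quantile normalization. The submitters' notes name limma for this without a version. Column medians in that table ran from 132 to 137, and its columns correlated with the raw median signal at r between 0.978 and 0.9998.

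The processed signal was used. Spots marked non-uniform or as population outliers were left out. The other signals were divided by the 75th percentile of the array, raised to a floor of 0.025 of that percentile where lower, and put on the log2 scale. The common floor was needed because 4 MCF-7 arrays came from a scanner protocol that gives values at or below 0, where the others put a small positive number. Repeat spots of a probe were averaged.

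Of 41000 probes, 23958 were given a symbol of the RefSeq gene table (GRCh38.p14) through their transcript accession, 2755 through their symbol and 1032 through a synonym. The other 13255 kept the name in the array files. Of the 30173 names measured, 17659 were symbols of the gene table, and 253 more were lost to spot marks. Where a gene had several probes (7757 genes), the probe with the highest mean over all 60 arrays stood for it, and the other probes are given where they differed. A gene was tested when its probe was well above background, by the mark of the scanner software, on all 3 arrays of at least 1 group in the fit. That left 19889 genes in LNCaP, 19451 in prostaspheres, 17373 in MCF-7 and 22019 in the fit of all arrays.

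Group means were fitted with limma 3.58.1 in R 4.3.3, with 1 fit per cell system and 1 fit of all 60 arrays for differences between systems. Tests were two-sided moderated tests with empirical Bayes variances. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 11 treatment comparisons set each treated group against the control its labels name. Troglitazone has no control of its own and was set against the DMSO controls of T0901417, which share its slides. The only MCF-7 control is titled 0 h and is not time matched. The 8 differences of effects were tested as contrasts: ATRA, 9-cis-RA and AM580 against each other within a cell system, and 1 compound between systems. Intervals are 95% intervals from the same fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures.

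Before the data were examined, 21 gene lists were fixed. They cover androgen-induced and androgen-repressed genes, targets of vitamin D, retinoids, liver X receptors (LXR) and PPAR, cell cycle, cholesterol synthesis, fatty acid synthesis, endoplasmic reticulum (ER) stress, interferon response, hypoxia, immediate early and stress genes, and oestrogen-induced genes. The others hold luminal, basal, squamous, neuroendocrine, fibroblast, endothelial and immune markers. Each list was compared with the other genes by camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. Endothelial markers, with at most 1 member tested, could not be tested. The 220 list tests of the treatment comparisons and the 160 of the differences were adjusted within each comparison.

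The genes named were chosen by a rule also fixed beforehand. It takes known targets of each receptor whatever their result. It adds the 5 largest rises and the 5 largest falls among called genes with a gene table symbol and no overlap between the groups, and up to 4 called members of each list described. For DHT and calcitriol it takes the 5 genes called in both comparisons in the same direction and the 5 in opposite directions with the largest smaller change. For each difference of effects it takes the 3 largest called differences each way. Genes with an array at the floor were left out of these choices, known targets apart, a limit added after the data were seen, which passed over up to 4 larger rises and up to 3 larger falls in a treatment comparison. Genes on the Y chromosome and XIST are never named.

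Where no array of one group had the gene well above background, the fold is a lower bound. It is taken against the detection limit of those arrays, which is the lowest level marked well above background on each and at least the floor, or against their own level where that was higher. No spot was saturated. Signal over background limited the precision of dim genes, and 3 arrays per group limited the rest. The median standard error of a log2 change was 0.137 in LNCaP, 0.138 in prostaspheres and 0.108 in MCF-7. On simulated data with the same layout, the fits recovered 58 to 92% of 2-fold and 87 to 100% of 4-fold changes.

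Alternatives planned beforehand were normexp background correction, quantile normalization, no filter, the mean of all probes, the authors' table, slide as a random or a fixed block, the replicate number as a block, a fit of only the groups compared, an estimated correlation and leaving out each array in turn. Normexp was planned on mean signals, which 10 LNCaP arrays lack, and was run on median signals. Chosen after the data were seen were normexp with 35 extreme local backgrounds replaced, a lower floor of 0.003, gene table symbols only, scan day as a block, genes well above background on every array compared, a replicate block where the numbers pair, and calcitriol with 1 treated LNCaP array. Numbers paired the arrays in LNCaP 9-cis-RA and in MCF-7 ATRA only. The other replicate numbers were not treated as pairs.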

Results

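Messenger RNA was measured on 60 one-colour arrays that cover the human transcriptome, in 20 groups of 3 arrays. LNCaP cells, an androgen-responsive line from a prostate cancer metastasis, made up 39 arrays in 13 groups. They were treated for 24 h with DHT, calcitriol, ATRA, 9-cis-RA, AM580, T0901417 or troglitazone, or with vehicle. Prostaspheres, labelled only as such, made up 12 arrays and were treated with ATRA, calcitriol or vehicle. MCF-7 cells, an oestrogen-responsive breast cancer line, made up 9 arrays and were treated with ATRA or AM580, beside untreated cells at 0 h. The 75th percentile of the processed signal lay between 742 and 2352 on LNCaP arrays and between 127 and 233 on MCF-7 arrays. Between 45.3 and 74.5% of the spots on a LNCaP array were well above background. The lowest shares were on calcitriol replicate 1 (45.3%), DHT replicate 3 (47.7%) and calcitriol replicate 3 (50.3%). Arrays lay on 23 slides read on 9 days, and slides held few complete sets of treated and control arrays. A gene is called where its adjusted p was under 0.05. Each ± below not named an SD is a standard error of a log2 change (3 arrays per group), its spread pooled over the fit. A planned normexp background correction, disturbed by a few runaway local backgrounds on 5 arrays, gave all 21 counts lower by more than 1.5 times and is not repeated at each count.

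The first question was which LNCaP genes answered to androgen. DHT (dihydrotestosterone), the most potent natural ligand of the androgen receptor, raised the kallikrein protease genes KLK2 and KLK4 by 19.9-fold and 9.67-fold (log2 change 4.31 ± 0.15 and 3.27 ± 0.17, n = 3). KLK2 lies on chromosome 19 at 50873439 to 50880567 (GRCh38.p14). STYXL2 rose 12.9-fold and the sialyltransferase gene ST6GALNAC1 9.34-fold. NKX3-1, a homeobox factor of prostate epithelium, rose 7.95-fold, and KCNN2, a calcium-activated potassium channel, 6.43-fold. TMPRSS2, a membrane serine protease, rose 2.6-fold, and FKBP5, a co-chaperone of steroid receptors, 1.61-fold. All treated arrays lay above all control arrays for the 5 largest of these rises. Among genes with no array at the floor, the largest falls were in MYLK (2.8-fold), the collagenase gene MMP1 (2.72-fold), NXPE1 (log2 change -1.41), PABPC5 (-1.39) and MMP10 (2.5-fold). MYLK lost its call with an alternative background correction.

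KLK3, which encodes prostate-specific antigen, had 3 probes that parted with DHT. The brightest over all 60 arrays, which stands for the gene here and which the array files place on an alternatively spliced transcript, changed by -0.50 ± 0.63 in log2 (adjusted p = 0.76). The other probes rose by 5.07 and 6.33. Messages for the androgen receptor AR (-0.07 ± 0.20) and the vitamin D receptor VDR (-0.05 ± 0.12) were not called. CYP24A1, which encodes the enzyme that inactivates calcitriol, changed by 0.04 ± 0.19.

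Of the genes known to be induced by androgen, 21 of 27 tested rose with DHT and 0 fell, and 22 rose when adjusted over the list alone (median log2 change 0.77, adjusted p = 3.15e-42, and 1.19e-08 with an estimated correlation). Cell cycle genes rose together: 32 of 34 were higher and 0 lower (33 adjusted over the list alone, median 0.90, adjusted p = 4.27e-65, and 5.43e-06 with an estimated correlation). Among them were the mitotic kinase gene AURKB (3.38-fold), the replication licensing genes CDT1 (3.33-fold) and CDC6 (2.93-fold), and E2F1 (2.72-fold), a transcription factor of S-phase entry. The DHT controls had the lowest mean level of this list among the LNCaP control groups (-0.58, the others 0.02 to 0.95). The DHT group (0.40) lay within the range of those controls, and low control arrays were not tested as a cause here. Fibroblast markers fell, 3 of 9 called and 4 adjusted over the list alone, with VIM (vimentin) at -0.63 ± 0.10 (adjusted p = 0.0112 with an estimated correlation). The androgen-repressed list was not called (adjusted p = 0.143). In it 5 of 12 genes fell and 2 rose, as many adjusted over the list alone, among the falls them CAMK2N1 (-0.85 ± 0.15) and CCN3 (-0.71 ± 0.14), while those that rose were the glucuronidation genes UGT2B17 (0.90 ± 0.10) and UGT2B15 (0.58 ± 0.10). Calls on 4 more lists were lost with an estimated correlation. Cholesterol synthesis (5 of 23 higher, 6 adjusted over the list alone, adjusted p = 0.212 with an estimated correlation) included DHCR24 at 1.00 ± 0.17. Fatty acid synthesis had 4 of 16 higher and 1 lower, as many adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), with the elongase gene ELOVL5 at 1.06 ± 0.11. Immediate early genes had 3 of 12 lower, 4 adjusted over the list alone (adjusted p = 0.0878 with an estimated correlation), with IER3 at -0.91 ± 0.12. Interferon response had 2 of 25 higher and 3 lower, 2 and 8 adjusted over the list alone (adjusted p = 0.319 with an estimated correlation).

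In all, DHT changed 1610 of 19889 genes, 881 higher and 729 lower, 233 of them by more than 2-fold. Within the slides that held both groups the androgen-induced list had medians of 0.94 and 0.73, and within the scan days 0.91 and 0.72. Without DHT replicate 3 the falls numbered 385. The count was 749 with slide as a fixed block, 975 with normexp and extreme backgrounds replaced, and 3407 in a fit of these groups alone.

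The next question was what calcitriol, the hormonal form of vitamin D, changed in the same cells. CYP24A1 (chromosome 20, 54143538 to 54173986) rose 1160-fold (log2 change 10.19 ± 0.19, n = 3), from a signal that was well above background on 1 of 3 control arrays. KCNN2 rose 23.0-fold, TMPRSS2 7.19-fold, and TRPV6, an epithelial calcium channel, 6.05-fold. CYP2B6 (10.4-fold), the NADPH oxidase gene NOX1 (9.16-fold), CD24 (7.67-fold) and the ceruloplasmin gene CP (7.65-fold) also rose, although another CYP2B6 probe changed by -1.19. AR itself rose 2.73-fold (1.45 ± 0.20, adjusted p = 5.3e-06). STMN4 fell 4.75-fold, LRRC31 4.64-fold, HMGCS2, the gate enzyme of ketone body synthesis, 4.38-fold, the chemokine gene CX3CL1 3.87-fold and CIITA 3.79-fold, all treated arrays lying below all control arrays. LRRC31 and CIITA were well above background on 1 of 3 treated arrays. VDR (-0.43 ± 0.12) and FKBP5 (-0.23 ± 0.07) were called lower, but neither held its call in every fit without 1 array. KLK3 (0.64 ± 0.63) and IGFBP3 (-0.35) were not called, and the other KLK3 probes changed by -1.01 to -0.79.

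Vitamin D targets rose with calcitriol, 8 of 21 higher and 1 lower, and as many adjusted over the list alone (median 0.14, and 0.07 without control replicate 2, adjusted p = 2.94e-09, and 0.00553 with an estimated correlation). They included CAMP, which encodes the antimicrobial peptide cathelicidin (4.05-fold), and CLMN (2.57-fold). The other lists called in this comparison were lost with an estimated correlation. Cell cycle genes had 9 of 34 lower and 0 higher, 13 lower adjusted over the list alone (adjusted p = 0.269 with an estimated correlation), among them the mitotic genes KIF20A (-0.79 ± 0.11) and CCNA2 (-0.76 ± 0.11). Interferon response had 6 of 25 lower, 13 adjusted over the list alone (adjusted p = 0.269 with an estimated correlation), with IFITM1 at -0.72 ± 0.14. Hypoxia genes had 5 of 16 lower, 7 adjusted over the list alone (adjusted p = 0.196 with an estimated correlation), among them ADM (-0.82 ± 0.13) and EGLN3 (-0.77 ± 0.10). Cholesterol synthesis had 3 of 23 higher, 4 adjusted over the list alone (adjusted p = 0.404 with an estimated correlation), with INSIG1 at 0.80 ± 0.08. ER stress had 3 of 19 higher, 5 adjusted over the list alone (adjusted p = 0.351 with an estimated correlation), with CHAC1 at 1.13 ± 0.13. Luminal markers had 4 of 13 higher and 1 lower, 4 and 2 adjusted over the list alone, and their test pointed up with a mean of 0.51 while their median was -0.11 (adjusted p = 0.219 with an estimated correlation). FOS, an immediate early gene, rose 5.78-fold.

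Calcitriol changed 2113 of 19889 genes, 821 higher and 1292 lower, 257 by more than 2-fold. On slides that held both groups the vitamin D list had medians of 0.03, 0.12 and 0.19, and on the scan days 0.03 and 0.12. Rises numbered 523 without control replicate 1, and falls 789 and 848 without calcitriol replicates 1 and 3. The count was 1127 without control replicate 3, 696 with calcitriol replicate 2 as the only treated array, 960 in a fit of these groups alone and 3218 with the authors' table.

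The series title names an antagonism between androgen and vitamin D signalling, so DHT and calcitriol were compared. Of 457 genes called in both, 263 moved in the same direction and 194 in opposite directions (57.5% the same, Fisher's exact test, two-sided p = 0.0208, genes taken as independent). In total 77 genes rose with both (36.4 if lists were independent) and 186 fell with both (47.4). Another 120 rose with DHT and fell with calcitriol (57.2), and 74 the reverse (30.1). Without DHT replicate 3 the 186 became 112 and the 74 became 46 (47 without DHT control replicate 2). The 120 became 69 and 77 without calcitriol replicates 1 and 3, and 67 without calcitriol control replicate 3. Across all tested genes, which are not independent replicates, the log2 changes correlated at r = 0.034 (Spearman's rho 0.053). Among shared rises were KCNN2 (log2 change 2.69 with DHT and 4.52 with calcitriol), TMPRSS2 (1.38 and 2.85), STYXL2 (3.69 and 1.31) and BMP6 (1.45 and 1.24), a bone morphogenetic protein. HOXA9 fell in both by 1.26, a call that several alternatives lost. Among opposite calls were MMP1 (-1.44 with DHT, 2.86 with calcitriol), PIP (1.16 and -1.69), GLYATL2 (1.05 and -1.18), TM4SF1 (1.65 and -0.99) and the adrenoceptor gene ADRA2A (0.90 and -1.46).

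**Figure D1:**
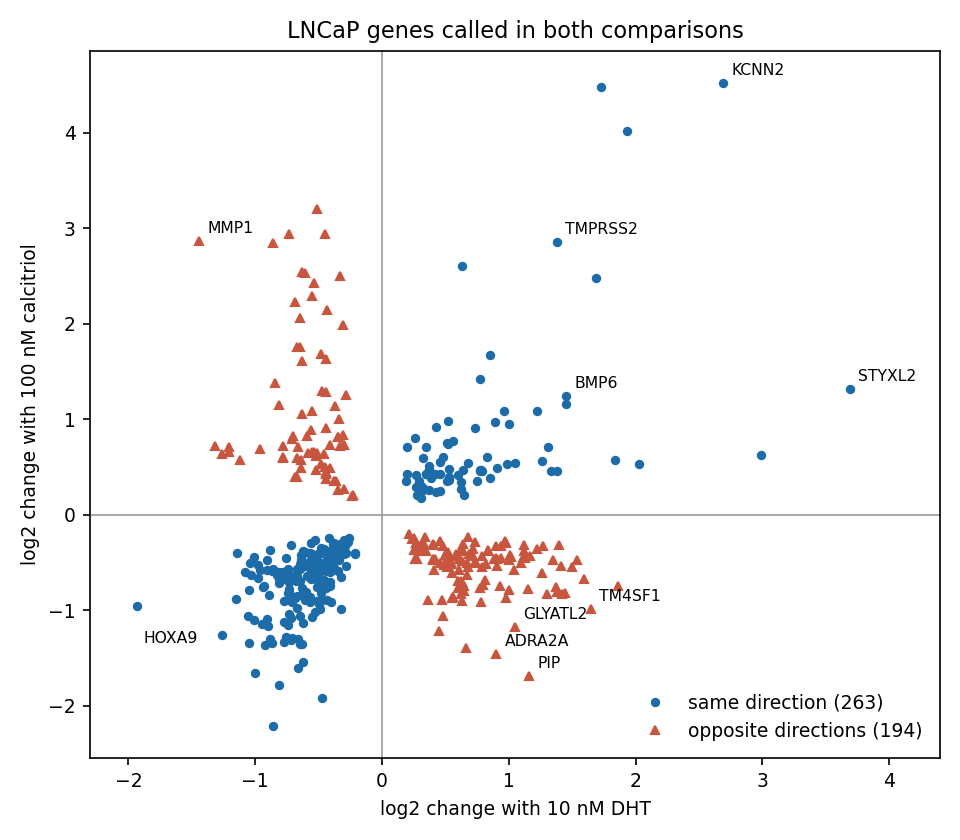
Log2 change with DHT (horizontal axis) against log2 change with calcitriol (vertical axis) in LNCaP for the 457 genes called in both comparisons. Circles are the 263 genes that moved in the same direction and triangles the 194 in opposite directions. Genes chosen by the fixed rule are named.

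As whole sets, the 881 genes that rose with DHT had a median log2 change of -0.07 under calcitriol (camera across genes, adjusted p = 0.5 over the 4 sets). The 729 that fell with DHT had a median of -0.13 under calcitriol, 34.6% of them above 0 (p = 0.00124, adjusted p = 0.00496, and adjusted p = 0.692 with an estimated correlation). The 821 genes that rose with calcitriol had a median of -0.005 and a mean of 0.01 under DHT, and their test pointed up (adjusted p = 0.558). The 1292 that fell with calcitriol had a median of -0.09 under DHT, 35.2% above 0 (p = 0.00282, adjusted p = 0.00564, and adjusted p = 0.828 with an estimated correlation). Same-direction calls numbered 131 with slide as a fixed block, 138 with normexp and extreme backgrounds replaced, 174 among genes well above background on every array compared, and 121 with calcitriol replicate 2 as the only treated array. Opposite calls numbered 82 with that block, 92 with that normexp and 79 with calcitriol replicate 2 alone. They numbered 129 without calcitriol control replicate 3 and 298 in fits of these groups alone. No array carried both ligands together, so a combined effect was not measured.

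Retinoids were tested in LNCaP with ATRA (all-trans retinoic acid), its geometric isomer 9-cis-RA, and AM580, a synthetic agonist of the retinoic acid receptor RARA, each at 100 nM for 24 h. ATRA raised CYP26A1, which encodes the main retinoic acid hydroxylase (chromosome 10, 93073475 to 93077885), at least 54.2-fold, from controls below the detection limit of their arrays (-4.92 in log2 of the share of the 75th percentile). DHRS3, a retinaldehyde reductase, rose 4.27-fold (2.09 ± 0.08, n = 3). Other rises were in the cadherin gene CDH26 (8.47-fold), NOX1 (5.84-fold), the cytokine gene IL1B (5.78-fold), the glycogen phosphorylase gene PYGL (5.33-fold) and CYP2B6 (4.68-fold, with 0.40 in log2 for another probe). HMGCS2 fell 4.59-fold, REG4 4.55-fold, ADRA2A 3.67-fold, the channel subunit gene KCNMB4 3.43-fold and GPC6 3.08-fold, the last losing its call with slide as a fixed block. RARA changed by 0.24 ± 0.17 (adjusted p = 0.56), CYP26B1 was at least 1.23-fold higher with a call that did not hold in every fit, and RARB and TGM2 lay at background.

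Retinoid targets rose with ATRA, 6 of 17 higher and 0 lower, and as many adjusted over the list alone (adjusted p = 3.35e-08, and 0.000327 with an estimated correlation), with the nuclear receptor corepressor NRIP1 (2.9-fold) and the epithelial factor ELF3 (1.88-fold) among them. Cell cycle genes rose with ATRA, 29 of 34 higher and 0 lower, 32 adjusted over the list alone (median 0.55, adjusted p = 6.37e-38, and 0.000327 with an estimated correlation). CDC6 rose 2.12-fold and the ribonucleotide reductase gene RRM2 1.81-fold. The vimentin gene VIM fell 2.61-fold and COL3A1, a fibrillar collagen, rose 2.32-fold. The lists called and then lost were androgen-repressed genes (1 of 12 higher and 3 lower, 2 and 4 adjusted over the list alone, with UGT2B15 at -0.78 ± 0.10), PPAR targets (2 of 13 lower, as many adjusted over the list alone, one of them HMGCS2) and fatty acid synthesis (3 of 16 higher and 1 lower, 6 and 2 adjusted over the list alone). Each was at adjusted p = 0.18 with an estimated correlation. In all 1365 genes were called, 706 higher and 659 lower, 156 by more than 2-fold. The retinoid list had a median of 0.43 on the slide that held both groups and 0.22 on the scan day that did, and 0.22 overall. Falls numbered 425 and 387 without ATRA replicates 1 and 3. The count was 234 with slide as a fixed block and 889 with normexp and extreme backgrounds replaced.

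With 9-cis-RA, CYP26A1 was at least 162-fold higher, and DHRS3 rose 4.24-fold (2.08 ± 0.08). CDH26 (21.7-fold, another probe at 1.35 in log2), PYGL (13.1-fold), NOX1 (12.9-fold), SHROOM1 (7.77-fold) and IL1B (5.67-fold) also rose. SLITRK6 fell 5.37-fold, KCNMB4 5.21-fold, TAFA2 5.06-fold (another probe at -0.21), the calcium channel gene CACNA1G 4.27-fold and the phosphatase gene PTPN21 4.17-fold. Neither CYP26B1 (0.03), RARA (0.08) nor RARB (-0.27, adjusted p = 0.11) was called. Cell cycle genes again rose, 32 of 34 (33 adjusted over the list alone, median 0.90, adjusted p = 6.52e-38, and 0.000654 with an estimated correlation), with RRM2 at 2.6-fold and the spindle checkpoint gene BUB1B at 2.51-fold. Fatty acid synthesis had 9 of 16 genes higher and 1 lower, as many adjusted over the list alone (adjusted p = 4.5e-05, and 0.0245 with an estimated correlation), among them the desaturase gene SCD (1.12 ± 0.23) and ACSL3 (0.83 ± 0.11). Their median was 0.45, and 0.29 without treated replicate 2. Retinoid targets had 4 of 17 higher and 2 lower, 5 and 2 adjusted over the list alone (median 0.07, adjusted p = 0.00364, and 0.0339 with an estimated correlation). MEIS1 (-0.61 ± 0.16) was one that fell. Their median was 0.009, 0.116 and 0 without control replicates 1 to 3, and 0.024, 0 and 0.176 without treated replicates 1 to 3. Androgen-repressed genes had 4 of 12 lower, 6 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). The bile acid and drug exporter gene ABCC4 rose 2.10 ± 0.16 in log2, and the only endothelial marker tested, VWF, fell by 1.9.

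These 9-cis-RA calls numbered 4972 (1749 higher, 3223 lower, 503 by more than 2-fold), but treated and control arrays lay on 1 slide each, so slide and treatment cannot be told apart. Pairing replicate numbers as a block called 7173 genes, and slide as a random block 8104. A fit of these groups alone, whose replicates differed by SDs up to 0.81 (0.39 in other LNCaP groups), called 269. Regroupings that kept the replicate 2 pair together called up to 8369.

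AM580 raised CYP26A1 at least 10.1-fold and DHRS3 2.79-fold (1.48 ± 0.08). CDH26 rose 8.36-fold (another probe at 0.60 in log2), PYGL 4.51-fold, SPRY4, an inhibitor of receptor kinase signalling, 3.13-fold and TRIM2 2.54-fold. KCNMB4 fell 2.69-fold, the lipocalin gene LCN2 2.56-fold, TAFA2 2.36-fold, MAP1B by 1.35 in log2 and MMP7 by 1.33. CYP26B1 (-0.02) and RARA (0.18, adjusted p = 0.75) were not called, and RARB (-0.70 ± 0.12) was called lower from treated arrays at the floor, a call several alternatives lost. Cell cycle genes rose, 14 of 34 and 0 lower (23 adjusted over the list alone, median 0.33, adjusted p = 2.52e-25, and 0.00756 with an estimated correlation), with CDC6 at 1.85-fold. Retinoid targets had 3 of 17 higher and 1 lower, as many adjusted over the list alone (median 0.10, adjusted p = 0.00221, and 0.0303 with an estimated correlation). AM580 changed 1168 genes, 549 higher and 619 lower, only 52 by more than 2-fold. On the slide that held both groups the retinoid list had a median of 0.16, and over all arrays it had 0.164 and 0.038 without control replicates 2 and 3, and 0.051 and 0.026 without AM580 replicates 2 and 3. Falls numbered 400 without control replicate 3. The count was 517 without AM580 replicate 3, 168 with slide as a fixed block and 1929 with slide as a random block.

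**Figure D2:**
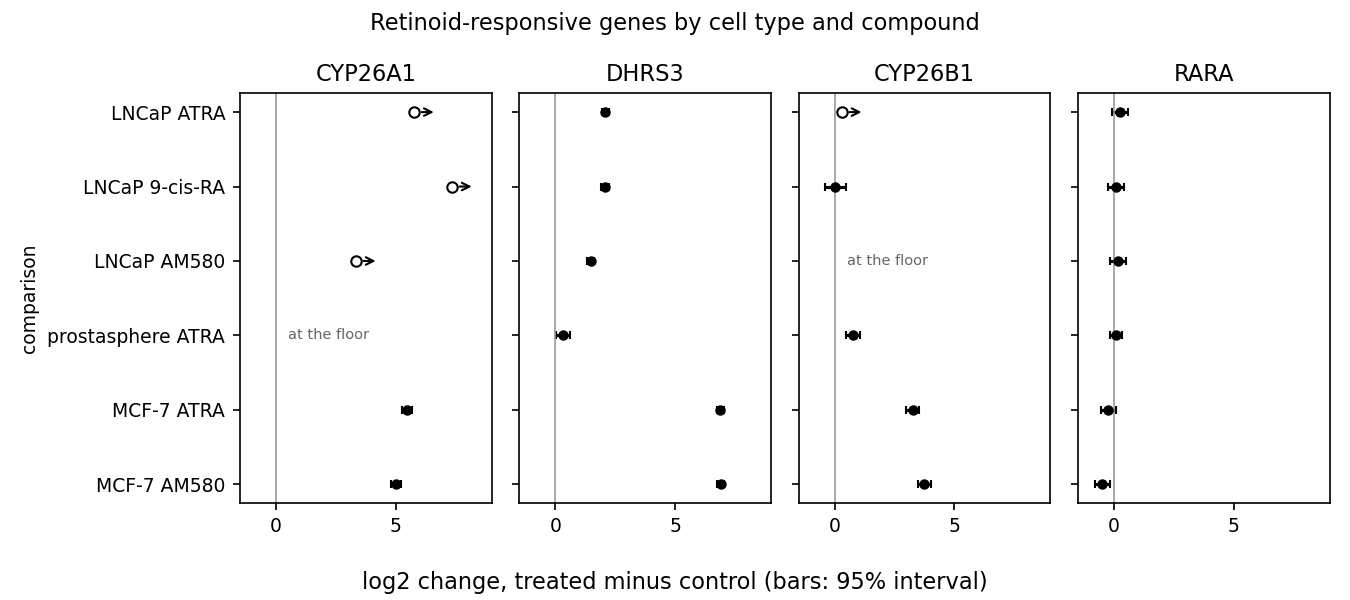
Log2 change, with its 95% interval, of CYP26A1, DHRS3, CYP26B1 and RARA in the 6 comparisons with a retinoid. Open circles with arrows are lower bounds where no control array was well above background, "at the floor" marks genes with no value, and DHRS3 was 2.09 with ATRA in LNCaP, 6.88 with ATRA in MCF-7 and 6.9 with AM580 in MCF-7.

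The 3 retinoids were then compared at their matched dose and time, effect against effect. ATRA and its isomer did not part on DHRS3, with a difference of 0.01 ± 0.11 in log2 (95% interval -0.21 to 0.23). AM580 gave less DHRS3 than ATRA by 0.61 ± 0.11 (interval 0.39 to 0.83, adjusted p = 0.0014) and less than 9-cis-RA by 0.60 ± 0.11 (0.38 to 0.82, adjusted p = 0.00077). CYP26A1 had no measurable control level. Its treated level, in log2 of the share of the 75th percentile, was 2.02 ± 0.21 with 9-cis-RA, 0.84 ± 0.12 with ATRA and -1.99 ± 0.40 with AM580 (SD, n = 3). For RARA the differences were 0.16 (-0.33 to 0.64), 0.06 (-0.43 to 0.55) and -0.10 (-0.58 to 0.39), none called. LCN2 rose by 1.81 with ATRA and fell by 1.36 with AM580, a difference of 3.16 ± 0.38, and it differed by 3.82 ± 0.38 between 9-cis-RA and AM580. SHROOM1 was lower with ATRA than with 9-cis-RA (-1.42 ± 0.15, interval -1.72 to -1.12), and higher with 9-cis-RA than with AM580 by 2.66 ± 0.15. VWF fell less with ATRA than with 9-cis-RA, by 1.42 ± 0.13. HMGCS2 fell further with ATRA than with AM580 (-1.37 ± 0.16), as did ADRA2A (-1.31), and SPRY4 was lower (-1.28).

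Between ATRA and 9-cis-RA 849 genes were called, 586 with a higher ATRA effect. Other differences were in CACNA1G (1.66 ± 0.42), MYBPC3 (1.41 ± 0.29), IGH (-1.67 ± 0.27) and H4C13 (-1.55 ± 0.39). Between ATRA and AM580 206 were called, 145 with a higher ATRA effect, CYP2B6 (2.21 ± 0.29) and PRSS1 (1.76) among them, although CYP2B6 lost its call with the mean of its probes. Between 9-cis-RA and AM580 1041 were called, 463 with a higher 9-cis-RA effect. SOWAHA (2.54 ± 0.44), ZFYVE9 (-1.97), ARHGEF25 (-1.60) and TMEM266 (-1.58) also differed, the last 3 losing their calls under several alternatives. Retinoid targets rose more with ATRA than with AM580 (4 of 17, as many adjusted over the list alone, adjusted p = 0.00688 with an estimated correlation). Cell cycle genes rose more with 9-cis-RA than with AM580 (14 of 34, 21 adjusted over the list alone), and so did fatty acid synthesis genes (4 of 16, 5 adjusted over the list alone), both at adjusted p = 0.00872 with an estimated correlation. Other lists called in these differences lost their calls with an estimated correlation. Of the genes not called, the 95% interval of the difference lay within 2-fold either way for 15709 of 19040 (82.5%) between ATRA and 9-cis-RA, 16784 of 19683 (85.3%) between ATRA and AM580, and 15502 of 18848 (82.2%) between 9-cis-RA and AM580.

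Differences from 9-cis-RA share its limits of slide and spread. The ATRA against 9-cis-RA count was 1402 without 9-cis-RA control replicate 3, 1699 and 1394 without 9-cis-RA replicates 2 and 3, 559 without ATRA control replicate 2, 477 and 522 without ATRA replicates 1 and 3, and 2600 with the 9-cis-RA pairs as a block. It was only 28 in a fit of the groups compared alone. The ATRA against AM580 count was 125 without AM580 replicate 3, 117 without ATRA replicate 3 and 56 with slide as a fixed block, and the 9-cis-RA against AM580 count was 1579, 1784 and 621 without 9-cis-RA replicates 2 and 3 and AM580 replicate 3.

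**Figure D3:**
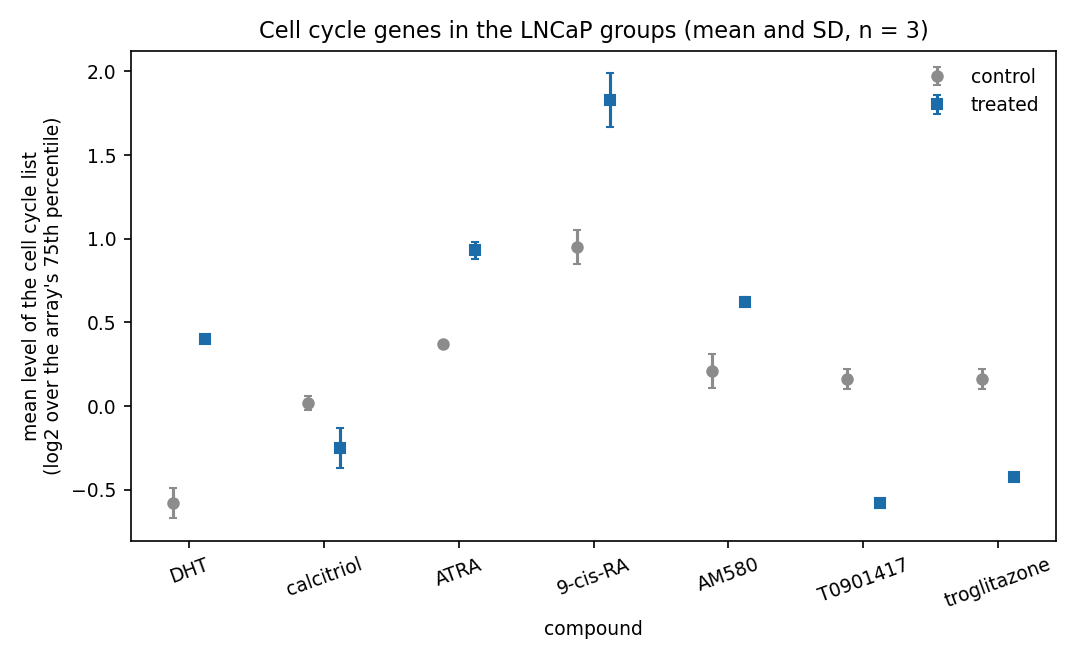
Mean level of the cell cycle list (log2 of the share of the 75th percentile of the array, mean ± SD of 3 arrays) in each treated LNCaP group and its control, troglitazone being set against the T0901417 controls. DHT and the 3 retinoids lie above their controls (DHT 0.40 against -0.58), and T0901417 (-0.58) and troglitazone (-0.42) below theirs (0.16).

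T0901417, spelled as in the labels, was used to ask which genes answer to the liver X receptor (LXR), a sensor of sterols. The cholesterol exporter genes ABCG1 (chromosome 21, 42199689 to 42297244) and ABCA1 rose 5.42-fold and 2.55-fold (2.44 ± 0.08 and 1.35 ± 0.16, n = 3). MYLIP, which encodes a ligase that degrades the LDL receptor, rose 3.05-fold, SREBF1, a driver of lipid synthesis, 1.9-fold, and SCD 2.51-fold. NIBAN1 (3.39 in log2), the phosphodiesterase gene PDE2A (7.19-fold), TAF5L (6.04-fold, another probe at -0.44 in log2) and SERPINA3 (5.11-fold) also rose. The largest falls were in DTL (7.29-fold, well above background on 1 of 3 treated arrays), MCM10 (6.41-fold), RRM2 (5.58-fold), MMP1 (5.48-fold) and E2F2 (4.58-fold, another probe at 0.05 in log2).

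LXR targets had 7 of 13 higher and 0 lower with T0901417, as many adjusted over the list alone (median 0.47, adjusted p = 1.66e-06, and 0.000232 with an estimated correlation). Fatty acid synthesis had 10 of 16 higher and 2 lower, as many adjusted over the list alone (median 0.61, adjusted p = 0.0023 with an estimated correlation). ER stress genes had 14 of 19 higher and 0 lower, 17 adjusted over the list alone (median 0.69, adjusted p = 0.000872 with an estimated correlation), among them CHAC1 (4.56-fold), DDIT3, a pro-apoptotic transcription factor (4.45-fold), and TRIB3 (3.06-fold). Cell cycle genes had 25 of 34 lower and 0 higher, 28 adjusted over the list alone (median -0.67, adjusted p = 0.000872 with an estimated correlation), with E2F1 at -1.89 ± 0.13. Interferon response had 7 of 25 lower, 8 lower and 2 higher adjusted over the list alone (adjusted p = 0.426 with an estimated correlation), with OAS3 at -0.79 ± 0.07. The immediate early genes IER3 (-1.78 ± 0.12) and EGR1 (-1.46 ± 0.19) fell and ATF3 (1.21 ± 0.09) rose. In all 3075 genes were called, 1538 higher and 1537 lower, 290 by more than 2-fold. The LXR list had medians of 0.44 and 0.52 on the slides that held both groups, and a fit of these groups alone called 6424 genes.

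Troglitazone, a thiazolidinedione ligand of the fatty acid sensor PPARG, was set against the same controls. Of the known PPAR targets chosen beforehand, PDK4 changed by 0.19 ± 0.22 (adjusted p = 0.79), and ANGPTL4, PLIN2 and FABP4 were not well above background on any array. The PPAR list missed its test, with 3 of 13 higher and 1 lower, as many adjusted over the list alone (median 0.11, adjusted p = 0.0578, and 0.343 with an estimated correlation). PLIN4, a lipid droplet protein gene, rose by 1.25 ± 0.19 and PCK1, a gluconeogenic enzyme gene, by 1.14 ± 0.12, while TXNIP fell by 0.53. PDE2A rose 7.07-fold, NIBAN1 6.62-fold, SERPINA3 4.16-fold, CHAC1 3.7-fold and S100P 3.5-fold. MCM10 fell 3.92-fold, RRM2 3.23-fold, DTL 3.14-fold, E2F2 3.06-fold (another probe at -0.13 in log2) and the exonuclease gene EXO1 2.84-fold. ER stress genes had 13 of 19 higher and 0 lower (16 adjusted over the list alone) and cell cycle genes 21 of 34 lower and 0 higher (30 adjusted over the list alone), both at adjusted p = 0.000544 with an estimated correlation. DDIT3 rose by 1.56 ± 0.12 and E2F1 fell by 1.35.

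Hypoxia genes had 1 of 16 higher and 8 lower with troglitazone, 1 and 9 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation), LDHA at -0.81 ± 0.07 and VEGFA, the one that rose, at 0.84 ± 0.09. Cholesterol synthesis had 6 of 23 lower, 8 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation), among them LDLR (-0.49 ± 0.09). Androgen-repressed genes had 3 of 12 lower, as many adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), UGT2B17 at -1.06 ± 0.10, and interferon response 4 of 25 lower, 4 lower and 3 higher adjusted over the list alone (adjusted p = 0.562 with an estimated correlation). Troglitazone changed 1309 genes, 667 higher and 642 lower, 97 by more than 2-fold. Its changes correlated with those of T0901417 at r = 0.777 across genes, where simulated groups without any treatment effect that share controls gave 0.499. The simulation held no slide differences, while both compounds had arrays on a common slide. The PPAR list had a median of 0.03 on the slide that held both groups, and its test passed without troglitazone replicate 1 (median 0.14), without control replicate 3 (0.10), and with slide as a random block (0.09) or the replicate number as a block (0.11). Falls numbered 395 without control replicate 2. The count was 866 without control replicate 1, 832 and 837 without troglitazone replicates 2 and 3, 305 with slide as a fixed block, 2176 with slide as a random block and 4515 in a fit of these groups alone.

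**Figure D4:**
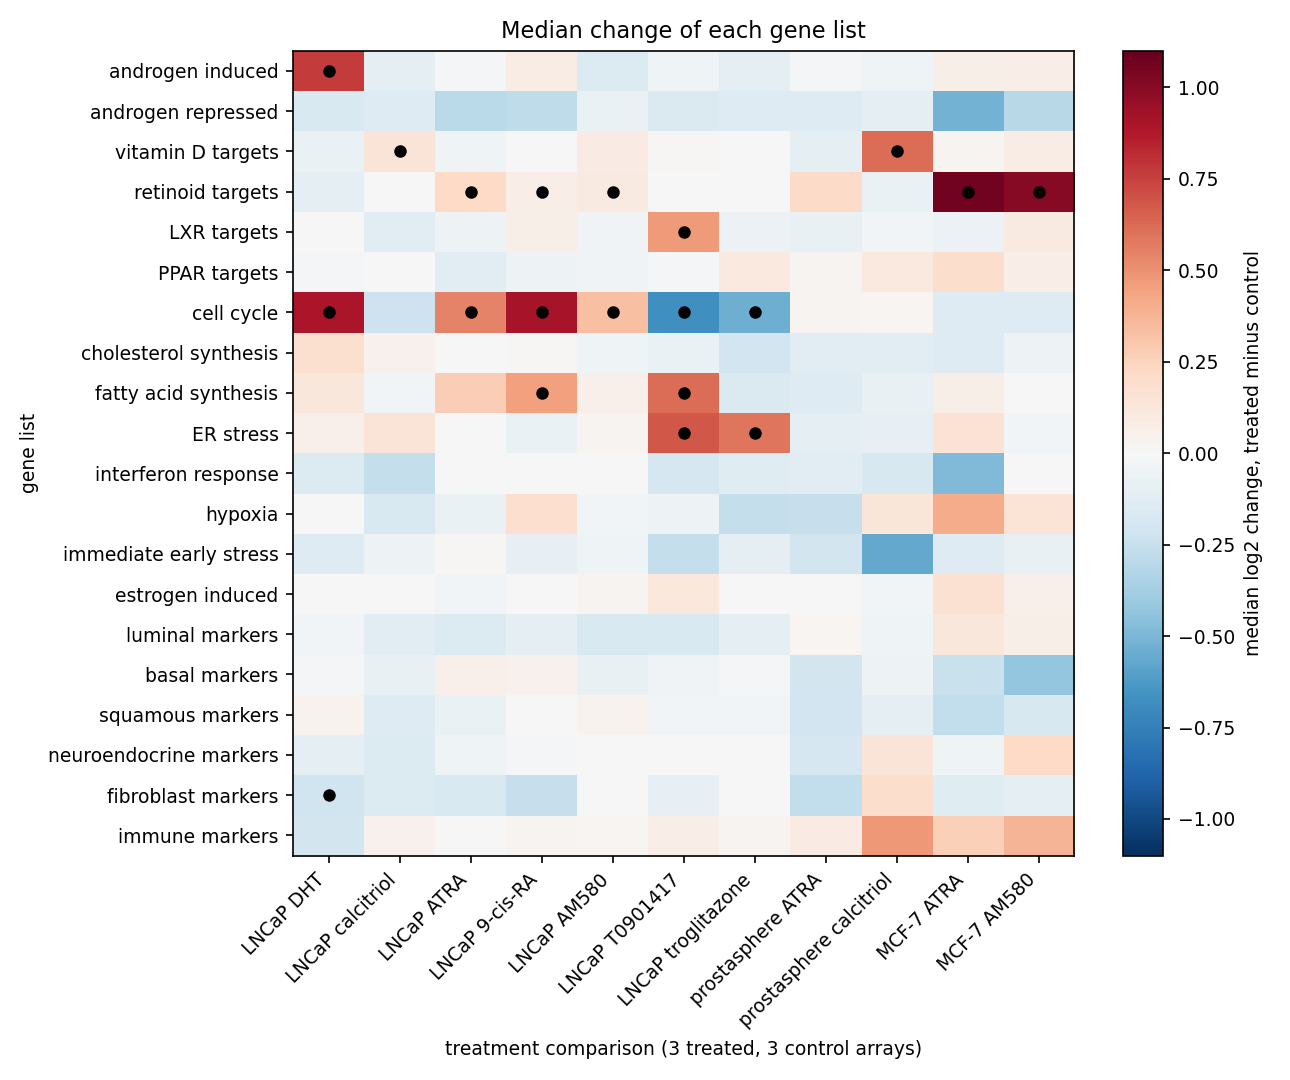
Median log2 change of 20 gene lists in the 11 treatment comparisons, red for higher and blue for lower, with a dot where the adjusted p with an estimated correlation was under 0.05. The endothelial list is left out because at most 1 member was tested, and the cell cycle list is among those with dots, higher with DHT (0.90) and lower with T0901417 (-0.67).

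In prostaspheres calcitriol raised CYP24A1 148-fold (7.21 ± 0.11, n = 3) and TRPV6 6.97-fold. The sulfatase gene SULF1 rose 11.6-fold, BMP6 8.66-fold, the IL-33 receptor gene IL1RL1 7.32-fold, the carbonic anhydrase gene CA2 5.9-fold and the thrombomodulin gene THBD 5.5-fold. The largest falls were NEFM (4.88-fold, another probe at -0.20 in log2), ANKRD1 (4.57-fold), RASD1 (4.11-fold), FOSB (4.01-fold) and SERPINB13 (3.94-fold). VDR changed by -0.33, a call lost without any of several arrays, and IGFBP3 by 0.61 (adjusted p = 0.15). Vitamin D targets had 15 of 29 higher and 1 lower, 16 and 1 adjusted over the list alone (median 0.61, adjusted p = 3.35e-12, and 0.00398 with an estimated correlation). Immediate early genes had 4 of 12 lower and 0 higher, 10 lower and 1 higher adjusted over the list alone (median -0.56, adjusted p = 0.0596 with an estimated correlation), FOS falling 2.47-fold. Immune markers had 1 of 4 higher, 3 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation), which was CD14, a monocyte marker that the vitamin D list also holds (4.42-fold). Cholesterol synthesis had 4 of 24 lower, 5 adjusted over the list alone (adjusted p = 0.533 with an estimated correlation), among them LDLR (-0.91 ± 0.15). COL1A1 rose 2.62-fold, TMPRSS2 2.82-fold, and the hypoxia genes LOX (2.14 ± 0.11) and CA9 (1.85 ± 0.23) rose while EGLN3 (-1.34 ± 0.12) fell.

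Prostasphere calcitriol gave 1870 calls among 19451 genes, 977 higher and 893 lower, 241 by more than 2-fold. The vitamin D list had a median of 0.62 on each of the slides that held both groups. Leaving out any 1 of the 6 arrays brought the count to between 895 and 1166 (942, 941 and 1166 without calcitriol replicates 1 to 3, and 944, 895 and 975 without control replicates 1 to 3), and a fit of these groups alone called 4243.

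ATRA in prostaspheres changed 59 genes, 26 higher and 33 lower, 13 by more than 2-fold. CYP26B1, the sister hydroxylase of CYP26A1, rose 1.7-fold (0.76 ± 0.13, n = 3), while CYP26A1 lay at the floor in both groups. DHRS3 (0.33), RARB (0.24), RARA and TGM2 were not called. The cytokine gene IL19 rose 2.31-fold, the kinase gene TXK by 1.19 in log2, GPRC5B by 1.1, GALNT12 by 0.99 and the angiopoietin gene ANGPT2 by 0.95. E2F2 fell 2.39-fold (another probe at 0.01), and HES5 (-1.21), NDP (-1.18), PXDNL (-1.11 ± 0.08) and MPIG6B (-1.11, another probe at 0.00) also fell. Retinoid targets had 1 of 24 higher, 6 adjusted over the list alone (median 0.21, and 0.13 without control replicate 1, adjusted p = 4.4e-05, and 0.238 with an estimated correlation). Hypoxia genes (0 of 18 called, 1 lower adjusted over the list alone, median -0.26) and squamous markers (1 of 14 lower, 4 adjusted over the list alone, TGM1 at -0.85 ± 0.11) were both at adjusted p = 0.53 with an estimated correlation. The retinoid list had medians of 0.17 and 0.12 on the slides that held both groups. The count rested on single arrays: it was 9, 6 and 5 without ATRA replicates 1 to 3, and 1379 and 31 without control replicates 1 and 3. It was 0 in a fit of these groups alone, where the full fit had 2933 genes at an unadjusted p under 0.05.

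MCF-7 cells answered both retinoids with large rises of known targets. ATRA raised DHRS3 (chromosome 1, 12567910 to 12618210) 118-fold (6.88 ± 0.07, n = 3), CYP26A1 44.4-fold and CYP26B1 9.58-fold, and STRA6, the retinol uptake receptor gene, 10.4-fold. The sphingomyelinase gene SMPD3 (46.9-fold), the angiogenin gene ANG (28.6-fold) and NPPC (28.3-fold, well above background on 1 of 3 control arrays) rose beside them. TNFRSF11B, which encodes osteoprotegerin, fell 13.7-fold, CLIC3 at least 11-fold, BMP5 9.82-fold, the fatty acid receptor gene CD36 9.44-fold and COL4A6 9.04-fold. AM580 raised DHRS3 120-fold (6.90 ± 0.07), CYP26A1 32.5-fold, SMPD3 27.4-fold, ANG 17.5-fold, the bradykinin receptor gene BDKRB2 15.2-fold, CYP26B1 13.5-fold and HOXA5 8.34-fold. It lowered BMP5 7.82-fold, CD36 7.13-fold, TNFRSF11B 7.07-fold, CLIC3 6.83-fold and COL4A6 6.34-fold. TGM2, a transglutaminase, rose 2.11-fold with ATRA and 2.03-fold with AM580. RARA changed by -0.23 and -0.48, the latter a call that several alternatives lost. TMPRSS2 rose 6.43-fold and 4.68-fold, and CYP24A1 5.31-fold with ATRA.

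Retinoid targets had 12 of 20 higher and 2 lower with ATRA, 12 and 3 adjusted over the list alone (median 1.06, adjusted p = 0.039 with an estimated correlation), and 13 higher and 3 lower with AM580, 14 and 3 adjusted over the list alone (median 1.00, adjusted p = 0.0368 with an estimated correlation). No other list called in MCF-7 held with an estimated correlation. Interferon response had 19 of 27 lower with ATRA, 20 adjusted over the list alone (adjusted p = 0.193 with an estimated correlation), with IFI44L at -1.06 ± 0.11 and IFIT3 at -0.82 ± 0.14. Hypoxia genes had 8 of 16 higher, 9 adjusted over the list alone, with NDRG1 at 1.47 ± 0.23 and HK2 at 1.45 ± 0.16, and ER stress 6 of 19 higher, 8 adjusted over the list alone, with ASNS at 1.31 ± 0.09, both at adjusted p = 0.316 with an estimated correlation. Androgen-repressed genes had 5 of 8 lower with ATRA, as many adjusted over the list alone (adjusted p = 0.193 with an estimated correlation) and 2 with AM580, as many adjusted over the list alone (adjusted p = 0.481 with an estimated correlation). Basal markers had 3 of 9 lower and 1 higher with ATRA, 5 and 1 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation) and 6 lower and 1 higher with AM580, as many adjusted over the list alone (adjusted p = 0.304 with an estimated correlation), among them the laminin gene LAMB3 (-1.30 ± 0.10 and -1.11 ± 0.10). Squamous markers had 5 of 11 lower and 1 higher with ATRA, 6 and 1 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation). Cell cycle genes had 1 of 34 lower with each compound, 0 adjusted over the list alone (adjusted p = 0.316 and 0.604 with an estimated correlation), and cholesterol synthesis 3 of 23 lower and 1 higher with ATRA, as many adjusted over the list alone (adjusted p = 0.391 with an estimated correlation).

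Counts in MCF-7 were 2224 of 17373 genes with ATRA (1054 higher, 1170 lower, 406 by more than 2-fold) and 2241 with AM580 (1275 higher, 966 lower, 382 by more than 2-fold). Medians of the retinoid list with ATRA were 1.01, 1.11 and 1.13 on the slides that held both groups. AM580 arrays shared neither slide nor scan day with the controls, so treatment and batch cannot be told apart. ATRA gave 1478 and 1451 calls without control replicates 1 and 3, and 2456 with its slide pairs as a block, and its rises numbered 681 without ATRA replicate 3. AM580 gave 1315 and 1419 without control replicates 1 and 3, and 6202 with normexp and extreme backgrounds replaced.

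Set against each other in MCF-7, ATRA and AM580 differed in 304 genes, 101 higher with ATRA and 203 lower. The AM580 arrays shared neither slide nor scan day with the ATRA arrays, so compound and batch cannot be told apart here. DHRS3 did not part them (-0.02 ± 0.07, interval -0.17 to 0.13), nor did TGM2 (0.05, -0.17 to 0.27), and CYP26A1 was higher with ATRA by 0.45 ± 0.09 (0.25 to 0.65, adjusted p = 0.048). CYP26B1 was -0.49 (-0.76 to -0.23) and not called (adjusted p = 0.08). Other differences were in GSTA2 (2.25 ± 0.19), the pepsinogen gene PGC (1.83 ± 0.10, from 5.53 with ATRA and 3.70 with AM580), CYP24A1 (1.59 ± 0.10, from 2.41 and 0.82), PANX3 (-1.16), TUBB2B (-1.11) and KRT84 (-1.11). GSTA2 turned to -0.10 with the planned normexp, and KRT84 lost its call under several alternatives. Interferon response was lower with ATRA (9 of 27, 18 adjusted over the list alone, adjusted p = 0.205 with an estimated correlation). Hypoxia genes (3 of 16, 7 higher and 1 lower adjusted over the list alone) and ER stress genes (1 of 19, as many adjusted over the list alone) were higher with ATRA, both at adjusted p = 0.291 with an estimated correlation. Both responses correlated at r = 0.803 across genes. Simulated untreated groups sharing controls, with no 0 to 24 h change, gave 0.502. Of the genes not called the interval of the difference lay within 2-fold for 15936 of 17069 (93.4%). The count was 122 and 104 without AM580 replicates 1 and 3, 69, 188 and 143 without ATRA replicates 1 to 3, 131 with no filter, 149 in a fit of these groups alone and 161 with slide as a random block.

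The last comparisons asked whether one compound acted alike in different cells, by testing the difference of its effects in a fit of all arrays. With ATRA, 1343 genes of 22019 differed between LNCaP and prostaspheres and 1968 between LNCaP and MCF-7. DHRS3 rose more in LNCaP than in prostaspheres by 1.77 ± 0.13 (adjusted p = 4.2e-14). Cell cycle genes rose more in LNCaP than in prostaspheres (16 of 34, 31 adjusted over the list alone, adjusted p = 0.00276 with an estimated correlation) and than in MCF-7 (27 of 34, 31 adjusted over the list alone, adjusted p = 0.000293 with an estimated correlation). Retinoid targets responded less in LNCaP than in MCF-7, 10 of 26 with a lower and 4 with a higher effect, 11 and 5 adjusted over the list alone (adjusted p = 0.000293 with an estimated correlation). Hypoxia genes had 8 of 18 with a lower effect in LNCaP than in MCF-7 (11 adjusted over the list alone, adjusted p = 0.0194 with an estimated correlation), and interferon response 10 of 27 with a higher one (12 adjusted over the list alone, adjusted p = 0.0451 with an estimated correlation). CDH26 rose by 3.08 in LNCaP and changed by -0.98 in MCF-7, and ANG and SMPD3 changed by -0.53 and 0.18 in LNCaP against 4.84 and 5.55 in MCF-7.

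AM580 effects differed between LNCaP and MCF-7 in 2165 genes, CDH26, by the probe used, again being higher in LNCaP (4.32 ± 0.20) and DHRS3 lower (-5.42 ± 0.13). Retinoid targets had 12 of 26 with a lower and 2 with a higher effect in LNCaP, 13 and 2 adjusted over the list alone (adjusted p = 2.96e-07 with an estimated correlation). Cell cycle genes had 16 of 34 with a higher effect in LNCaP (22 adjusted over the list alone, adjusted p = 0.0046 with an estimated correlation) and luminal markers 6 of 13 with a lower one, as many adjusted over the list alone (adjusted p = 0.0199 with an estimated correlation). Calcitriol effects differed between LNCaP and prostaspheres in 2866 genes. FOS rose by 2.53 in LNCaP and fell by 1.3 in prostaspheres, a difference of 3.84 ± 0.22. Immediate early genes had 5 of 12 with a higher effect in LNCaP, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0245 with an estimated correlation). Vitamin D targets had 10 of 29 with a lower and 3 with a higher effect in LNCaP, as many adjusted over the list alone (adjusted p = 0.0147 with an estimated correlation). The other lists called between systems were lost with an estimated correlation. Cell system, culture, control and slides all differ between these comparisons, and MCF-7 controls were not time matched. The ATRA count between LNCaP and prostaspheres was 2283 without prostasphere control replicate 1 and 342 with slide as a fixed block, and the ATRA count between LNCaP and MCF-7 was 983 with that block and 905 with normexp and extreme backgrounds replaced. Calcitriol calls between systems were 1540 with calcitriol replicate 2 as the only treated LNCaP array.

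Across the treatment comparisons, oestrogen-induced genes (lowest adjusted p = 0.166) and neuroendocrine markers (0.256) were called as a list in none, and endothelial markers could not be tested as a list. Camera tests a shift of a list in 1 direction and passes over mixed changes. In MCF-7, 9 of 23 oestrogen-induced genes rose and 7 fell with ATRA, 9 and 8 adjusted over the list alone. With AM580 6 rose and 5 fell, 8 and 9 adjusted over the list alone. Of all 17373 genes tested there, 2224 were called with ATRA and 2241 with AM580.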

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

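Each result here is an effect of one compound that differed between cell systems by a test of the difference itself, in the fit of all arrays and at an adjusted p under 0.05. Cell system, culture conditions, control and slides differ together between the systems, so no technical cause was set apart from a biological one. The real grouping of the arrays gave more genes than 99 others in each case, the highest other being given below. These others mix the arrays of one or both systems, so they do not test chance in the difference itself.

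ATRA effects differed between LNCaP and prostaspheres in 1343 genes, 842 of them higher in LNCaP, where the highest other regrouping of the arrays gave 1301 genes (1 of 100 regroupings, the real one, gave as many), and slide as a fixed block 342. Without prostasphere control replicate 1 the count was 2283. Effects in LNCaP were higher for IL36RN by 2.53 ± 0.23, PYGL by 2.53 ± 0.26 and PLA2G5 by 2.39 ± 0.25 (log2 difference, SE). They were lower for H4C5 (-2.57 ± 0.54), ZNF704 (-2.41 ± 0.56) and DNAJC22 (-1.93 ± 0.25), of which H4C5 lost its call with slide as a fixed block and both H4C5 and ZNF704 lost it in a fit of the groups compared alone.

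For ATRA in LNCaP against MCF-7, 1968 genes differed, 1027 of them higher in LNCaP, against 1520 in the highest other regrouping (1 of 100). CDH26 (4.07 ± 0.20), PYGL (3.02 ± 0.26) and PTHLH (2.89 ± 0.26) were higher in LNCaP. ANG (-5.37 ± 0.23), SMPD3 (-5.37 ± 0.24) and DHRS3 (-4.79 ± 0.13) were lower.

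AM580 gave 2165 such genes between LNCaP and MCF-7, 919 of them higher in LNCaP, against 1543 in the highest other regrouping (1 of 100). CDH26 (4.32 ± 0.20), UBE2E1 (3.17 ± 0.64) and PYGL (2.80 ± 0.26) were higher in LNCaP, and DHRS3 (-5.42 ± 0.13), SMPD3 (-4.96 ± 0.24) and ANG (-4.41 ± 0.23) lower.

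Calcitriol gave 2866 genes between LNCaP and prostaspheres, 1266 of them higher in LNCaP, against 1955 in the highest other regrouping (1 of 100). FOS (3.84 ± 0.22), ANXA2 (3.06 ± 0.62) and CYP2B6 (2.96 ± 0.34) were higher in LNCaP, and CAPN12 (-2.74 ± 0.26), SH3GL3 (-2.51 ± 0.30) and SEMA3B (-2.36 ± 0.21) lower.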

How the results depend on the processing

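Chosen after the data were seen were normexp with extreme backgrounds replaced, the lower floor, gene table symbols only, scan day as a block, genes well above background on every array compared, pairs as a block where the numbers pair, and calcitriol replicate 2 alone. All 21 counts stayed within 1.5 times with the mean of all probes and with gene table symbols only, and so did the 16 counts that could be fitted with scan day as a block. The medians of the principal lists stayed above 0 under every alternative run, except that of 9-cis-RA, which was 0 without control replicate 3 and without treated replicate 2. Named genes reversed in 27 cases, and fits without 1 array lost the call of a named gene in 624 cases and kept its result in 3750. In each list below, values follow the order of the report, and a comparison not named stayed within 1.5 times.

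Planned normexp gave 345 genes with DHT, 431 with calcitriol, 304 with ATRA, 1939 with 9-cis-RA, 196 with AM580, 946 with T0901417 and 246 with troglitazone in LNCaP. It gave 7 with ATRA and 1031 with calcitriol in prostaspheres, and 90 with ATRA and 62 with AM580 in MCF-7. For differences it gave 35 (ATRA against 9-cis-RA), 23 (ATRA against AM580), 65 (9-cis-RA against AM580), 0 (MCF-7 ATRA against AM580), 68 (ATRA, LNCaP against prostaspheres), 148 (ATRA, LNCaP against MCF-7), 756 (AM580, LNCaP against MCF-7) and 210 (calcitriol, LNCaP against prostaspheres). Same-direction calls of DHT and calcitriol were 33 and opposite calls 18. The normexp set higher with DHT passed the camera threshold under calcitriol at 0.00482, against 0.375 for the 881 genes. Normexp's construction shows part of the cause: 35 spots on 5 arrays, 18 of them on 1, had a local background far above their signal. With these replaced 12 of the 21 counts returned to within 1.5 times. With them replaced the moved counts were 975 (DHT), 889 (ATRA), 6202 (MCF-7 AM580), 431, 91 and 574 (the LNCaP retinoid differences in the order above), 905 (ATRA, LNCaP against MCF-7), 138 (same direction) and 92 (opposite). For these and for the moves that follow, the cause was not tested.

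Quantile normalization gave 96 genes for prostasphere ATRA, and the planned replicate block 5. No filter gave 37 for it and 131 for MCF-7 ATRA against AM580, and the lower floor gave 34 and 188, with 134 for LNCaP ATRA against AM580 and 718 for ATRA in LNCaP against prostaspheres. Slide as a random block gave 8104 (9-cis-RA), 1929 (AM580), 2176 (troglitazone), 90 (prostasphere ATRA), 2194, 376 and 2716 (the LNCaP retinoid differences) and 161 (MCF-7 ATRA against AM580). Slide as a fixed block gave 749 (DHT), 234 (ATRA), 168 (AM580), 305 (troglitazone), 19 (prostasphere ATRA), 56 (ATRA against AM580), 342 and 983 (ATRA, LNCaP against prostaspheres and MCF-7), 131 (same direction) and 82 (opposite), and could not be fitted for 9-cis-RA, MCF-7 AM580 or their differences. The authors' table gave 3218 (calcitriol), 478, 124 and 554 (the LNCaP retinoid differences), 153 (MCF-7 ATRA against AM580) and 815 (ATRA, LNCaP against prostaspheres).

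Fits of only the groups compared gave 3407 (DHT), 960 (calcitriol), 269 (9-cis-RA), 6424 (T0901417), 4515 (troglitazone), 0 (prostasphere ATRA), 4243 (prostasphere calcitriol), 28, 494 and 94 (the LNCaP retinoid differences), 149 (MCF-7 ATRA against AM580), 488 (ATRA, LNCaP against prostaspheres) and 298 (opposite). Genes well above background on every array compared gave 170 (MCF-7 ATRA against AM580), 792 and 1042 (ATRA, LNCaP against prostaspheres and MCF-7), 1185 (AM580, LNCaP against MCF-7), 1762 (calcitriol, LNCaP against prostaspheres) and 174 (same direction), with fewer genes tested. Pairs as a block gave 2600 (ATRA against 9-cis-RA) and 2541 (9-cis-RA against AM580), beside 7173 for 9-cis-RA and 2456 for MCF-7 ATRA. Calcitriol replicate 2 alone gave 696 (calcitriol), 1540 (LNCaP against prostaspheres), 121 (same direction) and 79 (opposite), the lone array being assumed to vary like the other groups and fewer arrays limiting the calls.

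With an estimated correlation, the set lower with DHT had a median of -0.133 under calcitriol (unadjusted p = 0.173, adjusted p = 0.692), the set lower with calcitriol -0.087 under DHT (unadjusted p = 0.414, adjusted p = 0.828), and the prostasphere ATRA retinoid list 0.207 (unadjusted p = 0.0119, adjusted p = 0.238). The troglitazone PPAR list passed with slide as a random block (median 0.091) and with the replicate block (0.106).

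Leaving out each array in turn gave 1129 to 1416 genes (DHT), 1127 to 3051 (calcitriol), 930 to 1229 (ATRA), 4423 to 6646 (9-cis-RA), 517 to 906 (AM580), 2230 to 2568 (T0901417), 832 to 1060 (troglitazone), 5 to 1379 (prostasphere ATRA), 895 to 1166 (prostasphere calcitriol), 1451 to 1825 (MCF-7 ATRA) and 1315 to 1929 (MCF-7 AM580). Differences ran from 477 to 1699, 117 to 204 and 621 to 1784 (LNCaP retinoids), 69 to 228 (MCF-7), 1008 to 2283 and 1691 to 1881 (ATRA, LNCaP against prostaspheres and MCF-7), 1704 to 2230 (AM580) and 2107 to 3196 (calcitriol). Same-direction calls ran from 181 to 304, opposite calls from 129 to 212, and the median of the PPAR list from 0.049 to 0.137. The arrays that moved a count, or a printed number of rises or falls, by more than 1.5 times are named in the report.

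Reversed log2 changes under planned normexp were CRABP2 (0.05), THRSP (0.05), COL3A1 (0.01) and ACTA2 (0.01) with DHT, ABCC4 (0.1), THBS1 (0.08) and COL1A1 (0.03) with calcitriol, COL3A1 (0.09) with T0901417 and TGM1 (0.03) with ATRA in MCF-7. With AM580 in MCF-7 they were SMPDL3A (0.27), TXNIP (-0.14), STARD4 (0.58), ASNS (-0.01), XBP1 (-0.01), PSMB9 (-0.26), TP63 (0.61), KRT13 (0.45) and S100A4 (0.18), and GSTA2 was -0.1 between ATRA and AM580. With extreme backgrounds replaced, ABCC4 (0.1), THBS1 (0.08), COL1A1 (0.03), TGM1 (0.03), STARD4 (0.11) and TP63 (0.16) stayed reversed. The mean of all probes turned KLK3 with DHT to 3.63 and ADCY9 with ATRA to -0.16. Planned normexp also moved the median of all genes by more than 0.1, from -0.004 to 0.097 (DHT), from -0.002 to 0.106 (T0901417), from 0.006 to -0.111 and from 0 to -0.135 (ATRA, LNCaP against prostaspheres and MCF-7), from -0.026 to -0.362 (AM580, LNCaP against MCF-7) and from -0.032 to 0.159 (calcitriol, LNCaP against prostaspheres). With extreme backgrounds replaced these 2 ATRA medians were again -0.111 and -0.135, and that of AM580 was -0.155.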

Other observations

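The tests of shared falls and the slide tests of the cell cycle list were chosen after their results were seen. The other tests below were chosen before.

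Overlaps between comparisons describe more of the biology. DHT and T0901417 moved many LNCaP genes in opposite directions: 499 genes were called oppositely where independent lists would give 124.46, while 53 rose with both (68.13 if independent) and 64 fell with both (56.34). Cell cycle genes were among those that parted, RRM2 at -2.48 and E2F1 at -1.89 with T0901417 and E2F1 at 1.44 with DHT, and ABCA1 went the other way (-1.15 with DHT, 1.35 with T0901417). The controls themselves differed, the mean level of the cell cycle list being -0.58 in the DHT controls and 0.16 in the T0901417 controls. DHT and ATRA shared 249 rises (31.27 if independent) and 144 falls (24.15), with 129 opposite calls (55.07). ATRA and calcitriol, both in LNCaP, shared 88 rises (29.14 if independent) and 202 falls (42.81), with 144 opposite calls (73.07). Shared falls included HMGCS2 (-2.20 and -2.13) and ADRA2A (-1.88 and -1.46).

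Among the LNCaP retinoids, ATRA and 9-cis-RA shared 502 rises (62.08 if independent) and 483 falls (106.79) with 12 opposite calls, and ATRA and AM580 shared 225 rises (19.49) and 209 falls (20.51). Calcitriol shared 110 rises (35.52 if independent) and 109 falls (42.91) between LNCaP and prostaspheres, TRPV6 and CYP24A1 among the rises, with 98 opposite calls (82.24). ATRA shared 136 rises (33.7) and 113 falls (29.26) between LNCaP and MCF-7, with 78 opposite calls (63.11). AM580 shared 62 rises (34.98) and 64 falls (22.39) between the same lines, with 79 opposite calls (56.75) and r = 0.044 across genes. Prostasphere ATRA, with few calls, shared 6 rises (0.59) and 1 fall (0.61) with LNCaP ATRA, with 4 opposite calls (1.2), and 10 rises (0.95) and 3 falls (0.65) with MCF-7 ATRA, with 1 opposite call (1.64).

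Other regroupings of the arrays were counted for each result. With 3 arrays against 3 there are 10 regroupings, too few for a share under 0.05. Real counts and the highest other were 1610 and 4 (DHT), 2113 and 298 (calcitriol), 1365 and 38 (ATRA), 1168 and 37 (AM580), 3075 and 4 (T0901417), 1309 and 6 (troglitazone), 59 and 10 (prostasphere ATRA), 1870 and 0 (prostasphere calcitriol), 2224 and 0 (MCF-7 ATRA), 2241 and 0 (MCF-7 AM580) and 304 and 0 (MCF-7 ATRA against AM580), the real grouping being the only 1 of 10 as large. For 9-cis-RA 4 of the 10 were as large as 4972, up to 8369, and those larger kept the replicate 2 pair on one side, which points to a shift shared by the replicate 2 arrays. Of the regroupings that part all 3 pairs, as the real one does, the others gave 15, 198 and 1. With the pairs as a block 7173 genes were called.

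For the principal lists, real medians and the highest other were 0.768 and 0.333 (DHT), 0.138 and 0.108 (calcitriol), 0.468 and 0.309 (T0901417), 0.106 and 0.096 (troglitazone), 0.207 and 0.165 (prostasphere ATRA), 0.615 and 0.232 (prostasphere calcitriol), 1.064 and 0.444 (MCF-7 ATRA) and 0.998 and 0.372 (MCF-7 AM580), each the largest of 10. In LNCaP, 2 of 10 were as large for ATRA (0.218, other 0.245), 3 for 9-cis-RA (0.073, other 0.176) and 2 for AM580 (0.096, other 0.096). The sets of DHT-called genes under calcitriol had 0.07 against 0.062 (higher) and 0.133 against 0.087 (lower), and the sets of calcitriol-called genes under DHT 0.005 against 0.028 (higher, 8 of 10 as large) and 0.087 against 0.061 (lower). For a difference of effects, a regrouping that mixes the arrays of one compound and keeps the other brings that whole effect into the difference, so these counts do not test chance in the difference. Of 100 regroupings, 32 gave as many as 849 for ATRA against 9-cis-RA (up to 6594), 6 as many as 206 for ATRA against AM580 (up to 658) and 30 as many as 1041 for 9-cis-RA against AM580 (up to 5175). Where both compounds were mixed, ATRA against AM580 gave at most 12. The differences from 9-cis-RA then gave at most 36 (ATRA) and 35 (AM580) in regroupings that part all 3 of its pairs, and the larger counts came from those that kept a pair on one side. Calls shared by DHT and calcitriol numbered 263 in the same direction (highest other 11) and 194 in opposite directions (highest other 12), the real grouping being the only 1 of 100 as large. Regrouping the DHT arrays left at most 4 DHT calls, and regrouping the calcitriol arrays at most 298 calcitriol calls. The shared counts therefore fall with the lists themselves, and this does not test chance in the sharing.

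More genes fell with both DHT and calcitriol than independent lists give, 186 (112 without DHT replicate 3) or 3.93 times the independent number, and the factor stayed between 2.99 and 5.68 without any 1 array. Both treated groups held arrays with a higher background, which could lower dim genes in both, but among genes well above background on all 12 arrays the factor was 4.14 (2.93 to 6.43 without 1 array). With slide as a fixed block the lists were shorter, and the factor was 6.65 (5.47 to 11.39). Shared rises (2.12 times, 2.88 with the block) and opposite calls (2.22, 2.79) were also above the independent number. Part of the excess may thus come from genes that change readily. No array carried both ligands, so no biological explanation was tested.

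Cell cycle genes rose with each of the 3 retinoids in LNCaP. With slide as a fixed block the list median was 0.527 for ATRA and 0.281 for AM580, with few members called. For ATRA this rests on the 1 slide that held both groups, with 1 array of each. For AM580 it rests on 1 control array beside 3 treated arrays. Single arrays cannot part a treatment effect from differences between arrays, so whether slide differences were the whole cause stays undecided. For 9-cis-RA (0.904) slide and treatment cannot be told apart, since each group lay on a slide of its own. List means of the retinoid-treated groups lay at least 0.46 above the highest control group of the other comparisons (larger SD 0.16). But LNCaP control groups ranged from -0.58 to 0.95, and the 9-cis-RA controls (0.95) lay above the ATRA-treated (0.93) and AM580-treated (0.62) groups. This comparison therefore cannot exclude low control arrays for ATRA and AM580. Nor can it for 9-cis-RA (controls highest, treated 1.83), whose arrays shared no slide or scan day with other groups. Growth-promoting retinoid action in starved LNCaP cells is a candidate explanation that these arrays, which hold no count of cells or of phases, leave untested.

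KLK3 probes parted with DHT. The brightest over all 60 arrays had a level of -0.63 ± 0.36 with DHT and -0.14 ± 0.19 in controls, and the others 1.65 ± 0.07 against -3.42 ± 0.12 and 2.97 ± 0.26 against -3.36 ± 0.25 (log2 of the share of the 75th percentile, SD, n = 3). Saturation is argued against by 0 saturated spots of this probe on the 6 arrays, where its level with DHT lay below that of the others, and background noise by the probes that rose being well above background in 6 of 6 cases on the DHT arrays. The array files place the probe that did not rise on an alternatively spliced transcript, so a transcript that androgen leaves unchanged may be what it reads, which no value here tests. The mean of all probes gave 3.63 (adjusted p = 1.1e-11).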
